A study of Homo sapiens with 24 samples.

How the data were processed

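RNA from MCF10A cells, an established human breast epithelial line that does not form tumours, was hybridised to Affymetrix Human Gene 1.0 ST arrays. The 24 arrays formed 12 groups of 2 replicates, which the labels call biological, from 3 transfections at 4 times. Cells received a non-targeting control oligonucleotide (control), one directed at miR-20a (si-miR-20a) or one directed at miR-671-5p (si-miR-671), and RNA was taken at 0, 30, 60 and 120 min of EGF. The protocol text also names miR-212, for which none of the 24 samples carried a label, so it was not analysed here. Whether the replicates came from separate transfections or days was not given in the sources used here.

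The authors deposited log2 values, 1 per Affymetrix transcript cluster, called a probe set here. Their processing notes name Affymetrix Expression Console without a version, and the summarisation algorithm, background correction and normalization were not given in the sources used here. The base of the logarithm was read from the values, whose array maxima lay between 13.0 and 13.2. The array medians ran from 6.56 to 6.57, the lower quartiles from 4.95 to 4.97 and the upper quartiles from 8.26 to 8.28, so the arrays had nearly the same distribution as deposited. The table held 33297 probe sets with 0 missing values and 0 value columns of no sample, and the values were used without further normalization.

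Probe sets were named from a table of their genes. Of all probe sets, 19460 had exactly 1 gene symbol and were tested, covering 18417 genes, 769 of them with more than 1 probe set. Another 1754 had several symbols and 12083 were not listed in that table, and both kinds were left out except in the setting that tested all probe sets. A match by gene ID to a reference table covered 19429 probe sets and changed 0 symbols. Genes are given by symbol, and genome positions were not used here.

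The model was limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group over all 24 arrays and no replicate block, then eBayes, with 12 residual and 2.57 prior degrees of freedom and a prior SD of 0.136. Benjamini-Hochberg adjustment ran over the 19460 probe sets, and a call was an adjusted p under 0.05. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The comparisons were EGF at each time against 0 min in control and averaged over the transfections, each transfection against control at each time and averaged over times, and si-miR-20a against si-miR-671 averaged over times. A difference of the EGF response between a transfection and control was tested with limma's moderated F over its 3 times. Errors are standard errors of the model unless they are named otherwise.

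Replicate numbers did not pair the samples. Over the 66 pairs of groups, the correlation of the differences between replicates ran from -0.57 to 0.55 with a median of 0.063, and 30 of the pairs lay above 0.1. The fit with the replicate number as a block is therefore given only beside the other settings. With 2 arrays against 2, the smallest exact permutation p is 0.33, so single-time comparisons rest on the spread pooled over all groups.

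The lists of genes, the rule for naming genes, the comparisons and most of the other settings were fixed before the data were examined. Each gene was represented by its probe set with the highest mean over the 24 arrays. For each main comparison the rule took the 10 largest rises and the 10 largest falls past the threshold that went the same way in every pairing of replicates, or at every time mean for averages, up to 4 members of each list past the threshold, the 10 smallest p for differences of the response, and MIR17HG in every case. Where under 5 passed in a direction, it took up to 5 with the smallest p. Genes named outside that rule are members of the lists or were chosen after their values were seen.

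The lists were immediate early transcription factors, delayed early and feedback attenuators, EGF family ligands, ERBB receptors, cytokines and NF-kappaB feedback, adhesion, matrix and invasion, transcripts that growth factors lower, miR-17 family targets from earlier literature, miR-671-5p targets from earlier literature, microRNA host and primary transcripts, small RNA silencing machinery, interferon response, mitosis, G1/S and DNA replication, cholesterol synthesis, p53 targets, unfolded protein and amino acid stress, heat shock, and basal epithelial, luminal epithelial, mesenchymal and fibroblast, and blood and endothelial markers. They were tested with limma's camera at a preset correlation of 0.01, adjusted over 22 lists within a comparison, beside camera with an estimated correlation, fry, and an exact permutation test of a score per array. The permutations were stratified by time (1296, smallest two-sided p 0.0015) or by transfection (216, smallest two-sided p 0.0093). Their p is given unadjusted and tests a list's own shift, not its shift against other genes. A list of mitochondrially encoded mRNAs had 0 of 13 members measured and was not tested. No sequence of the 3 prime UTRs was held, so the planned test of seed sites was not run.

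The pipeline was tested on simulated data. In 2 simulated comparisons of 2 arrays against 2, 76% and 82% of changes of 1 on the log2 scale were called, and 2% of changes of 0.3 in both. In 2 of 8 against 8, the shares were 100% and 96% for changes of 1, and 44% and 40% for changes of 0.3. False calls made up between 2.54% and 5.42% of the called probe sets. Of 20 simulated lists, camera called the 1 that had been moved by 0.2 and 0 of the unmoved ones. The simulated probe sets varied independently, so this does not show how often camera calls unmoved lists whose genes vary together. The moderated F found 49% of differences of 1 and 84% of differences of 2, so small differences of the response stay below what these arrays can show.

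The other settings were quantile normalization, centring on array medians, a filter on dim probe sets, all probe sets, eBayes with trend and robust, array weights, only the groups compared, the replicate block, leaving out each array, a fold of at least 1.5, the mean of a gene's probe sets, leaving out each time, camera with an estimated correlation, fry, and the controls split by replicate number. Chosen after seeing the data were a covariate from the olfactory receptor probe sets, 1 probe set per gene, averages over pairs of times, and EGF averaged over control and si-miR-20a alone. The log2 of the value plus 16 did not apply, as the values were log2 already. The arrays' number limits the precision of every value.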

Results

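Gene expression was measured on 24 arrays of MCF10A cells, with 3 transfections (control, si-miR-20a and si-miR-671) at 0, 30, 60 and 120 min of EGF and 2 replicates in each of the 12 groups. Values are log2 levels per probe set. Across probe sets, which are not independent replicates, the correlation between the 2 replicates of a group ran from 0.973 to 0.992 and the SD between them from 0.163 to 0.305. The mature miR-20a and miR-671-5p were not measured, so the arrays cannot show by how much either oligonucleotide lowered its target.

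The control arrays show which transcripts changed over the minutes of EGF while neither microRNA was targeted. No arrays without EGF at matching times were among the groups. EGF responses here are therefore changes against 0 min, from which effects of time or handling cannot be told apart. By 30 min the immediate early transcription factors had risen: FOSB by 5.18 ± 0.25 on the log2 scale (36.3-fold, SE, n = 2 arrays per group) and EGR3 by 3.96 ± 0.18. FOS rose by 3.69 ± 0.15, from 7.21 to 10.9, and EGR1 by 3.08 ± 0.16. DUSP1 (2.46 ± 0.09) and DUSP5 (1.81 ± 0.13), phosphatases that switch off MAP kinases, rose beside them, as did ZFP36 (2.36 ± 0.14), which speeds the decay of short-lived mRNAs. PTGS2, the inducible cyclooxygenase, rose by 2.40 ± 0.12, the cytokine LIF by 1.33 ± 0.11, and the matrix-associated CCN2 and CCN1 by 2.70 ± 0.08 and 1.69 ± 0.10. HBEGF, itself a ligand of the EGF receptor, rose by 0.80 ± 0.08.

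By list, 15 of 26 measured immediate early transcription factors were higher at 30 min and 11 did not pass, or 20 higher adjusted over the list alone. Limma's camera called the list (adjusted p = 2.4e-108, and adjusted p = 5e-07 with an estimated correlation). Of 29 delayed early and feedback attenuators, 8 were higher, or 14 adjusted over the list alone (adjusted p = 7.7e-05 with an estimated correlation). Of 18 members of the cytokine and NF-kappaB feedback list, 5 were higher, or 8 adjusted over the list alone (adjusted p = 0.00032 with an estimated correlation). Of 19 adhesion genes 3 were higher, CCN1, CCN2 and F3, or 4 adjusted over the list alone (adjusted p = 0.0016 with an estimated correlation). HBEGF was the single ligand of 7 called by either count, and the ligand list's call was lost (adjusted p = 0.056 with an estimated correlation). GADD45B (1.15 ± 0.15), PPP1R15A (0.88 ± 0.11) and PLK3 (0.63 ± 0.10) were the single members called among 27 transcripts that growth factors lower, 18 unfolded protein and amino acid stress genes and 18 p53 targets.

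At 30 min limma called 65 of 19460 probe sets, 64 of them higher, FOSB the most. The 1 fall was that of PLEK, by 0.70 ± 0.12 (adjusted p = 0.012). PLEK was no longer called without control 0 min replicate 1 (0.14) or 2 (0.1) or control 30 min replicate 2 (0.2). PLK3 lost its call without any 1 of the 4 arrays (0.081 to 0.16), and F3 without control 0 min replicate 1 (0.095) or control 30 min replicate 1 (0.07) or 2 (0.054). The count was 38 without control 0 min replicate 1, 40 without control 30 min replicate 2 and 10 in a fit of the 4 arrays alone.

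At 60 min the same lists stood higher and the ligand list joined them. FOSB lay 5.31 ± 0.25 and EGR3 4.89 ± 0.18 above 0 min, PTGS2 3.49 ± 0.12, NR4A1, an orphan nuclear receptor, 3.69 ± 0.24, and DUSP5 2.46 ± 0.13 (n = 2 arrays per group). IL24 rose by 1.80 ± 0.12, IL1A by 0.87 ± 0.10, HBEGF by 1.25 ± 0.08, and PLAUR, the urokinase receptor, by 0.85 ± 0.09. Of the immediate early list 19 of 26 were higher, or 23 adjusted over the list alone (camera adjusted p = 2.8e-80, and adjusted p = 2.7e-06 with an estimated correlation). Of the feedback attenuators 13 of 29 were higher, or 16 adjusted over the list alone (adjusted p = 0.00016 with an estimated correlation). Of the 7 ligands HBEGF and EREG were higher, or 3 adjusted over the list alone (adjusted p = 0.038 with an estimated correlation). The cytokine list had 6 of 18 higher, or 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.0083 with an estimated correlation). The adhesion list had 6 of 19 higher, or 7 adjusted over the list alone (adjusted p = 0.0014 with an estimated correlation).

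Limma called 154 probe sets at 60 min, 147 higher and 7 lower. The named falls were EBLN1 by 1.88 ± 0.34, LRCH2 by 1.18 ± 0.24, NLRC4 by 1.13 ± 0.23, CNR2 by 0.96 ± 0.21 and POLE2 by 0.84 ± 0.18, from levels of 6.16 or less at 0 min. LRCH2 (0.16 to 0.27), NLRC4 (0.11 to 0.28), CNR2 (0.16 to 0.39) and POLE2 (0.056 to 0.42) lost their calls without any 1 of the 4 arrays compared. EBLN1 lost its call without control 0 min replicate 1 (0.057) or 2 (0.13) or control 60 min replicate 2 (0.21). The rise of EREG, 0.86 ± 0.15, was not called either without any 1 of the 4 arrays (0.056 to 0.13). The count was 101 without control 0 min replicate 2, 102 and 93 without control 60 min replicates 1 and 2, and 25 in a fit of the 4 arrays alone.

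At 120 min the response held growth factor, cytokine and invasion genes and, for the first of these times, many falls. FOSL1, an AP-1 subunit, rose by 2.33 ± 0.13, IL24 by 2.76 ± 0.12, and SEMA7A by 2.31 ± 0.25 (n = 2 arrays per group). SPRY4 (2.15 ± 0.14) and DUSP6 (1.62 ± 0.08), inhibitors of ERK signalling, rose with them. The ligands EREG (1.95 ± 0.15), TGFA (1.39 ± 0.08), NRG1 (1.34 ± 0.13) and HBEGF (0.95 ± 0.08) rose, 4 of 7, or 5 adjusted over the list alone (camera adjusted p = 0.0025 with an estimated correlation). PLAUR rose by 1.57 ± 0.09 and CCN2 by 2.24 ± 0.08. Of 19 adhesion genes 8 were higher, or 11 adjusted over the list alone (adjusted p = 0.00057 with an estimated correlation). Of the immediate early list 17 of 26 were still higher and HES1 was lower by a log2 change of -1.08 ± 0.08. The counts adjusted over the list alone were 22 and 1 (adjusted p = 0.00028 with an estimated correlation). Of the feedback attenuators 16 of 29 were higher, with SOCS3 at -1.17 ± 0.15 and DUSP1 at -0.42 ± 0.09 lower. These were 18 and 2 adjusted over the list alone (adjusted p = 0.00057 with an estimated correlation).

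In control 154 probe sets were lower at 120 min. ELF3, an epithelial transcription factor, fell by 2.50 ± 0.17, from 8.60 to 6.10 (n = 2 arrays per group). DDIT4, an inhibitor of mTORC1, fell by 1.90 ± 0.14, the ephrin EFNA1 by 1.75 ± 0.09 and the hypoxia-responsive ADM by 1.51 ± 0.14. NFKBIA and TNFAIP3, which restrain NF-kappaB, fell by 1.65 ± 0.14 and 1.41 ± 0.09 and the chemokine CXCL8 by 1.44 ± 0.19. The cytokine list thus split into 5 higher and 8 lower of 18 (5 and 9 adjusted over the list alone), and camera did not call it (adjusted p = 0.057). PIK3IP1 (-1.49 ± 0.12), TXNIP (-1.45 ± 0.10) and BCL6 (-1.25 ± 0.18) were among 9 of 27 transcripts that growth factors lower that fell, while PER2 and IRS2 rose. Adjusted over the list alone 5 were higher and 9 lower (camera adjusted p = 2.3e-05), and that call was lost (adjusted p = 0.066 with an estimated correlation).

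Cell cycle genes were lower as lists at 120 min. The mitosis list had TOP2A (-0.39 ± 0.09) and TTK (-0.76 ± 0.18) lower of 25, or 6 adjusted over the list alone (camera adjusted p = 0.018 with an estimated correlation). The G1/S list had MCM3 (-0.34 ± 0.07) and ORC1 (-0.65 ± 0.12) lower of 25, or 7 adjusted over the list alone (adjusted p = 0.013 with an estimated correlation). Each of these 4 genes lost its call without 3 of the 4 arrays compared, TOP2A at 0.079 to 0.25, TTK at 0.17 to 0.37, MCM3 at 0.091 to 0.14 and ORC1 at 0.054 to 0.077. Limma called 576 probe sets at 120 min, 422 higher and 154 lower. The count was 344 and 312 without control 0 min replicates 1 and 2, 314 without control 120 min replicate 1 and 39 in a fit of the 4 arrays alone.

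**Figure D1:**
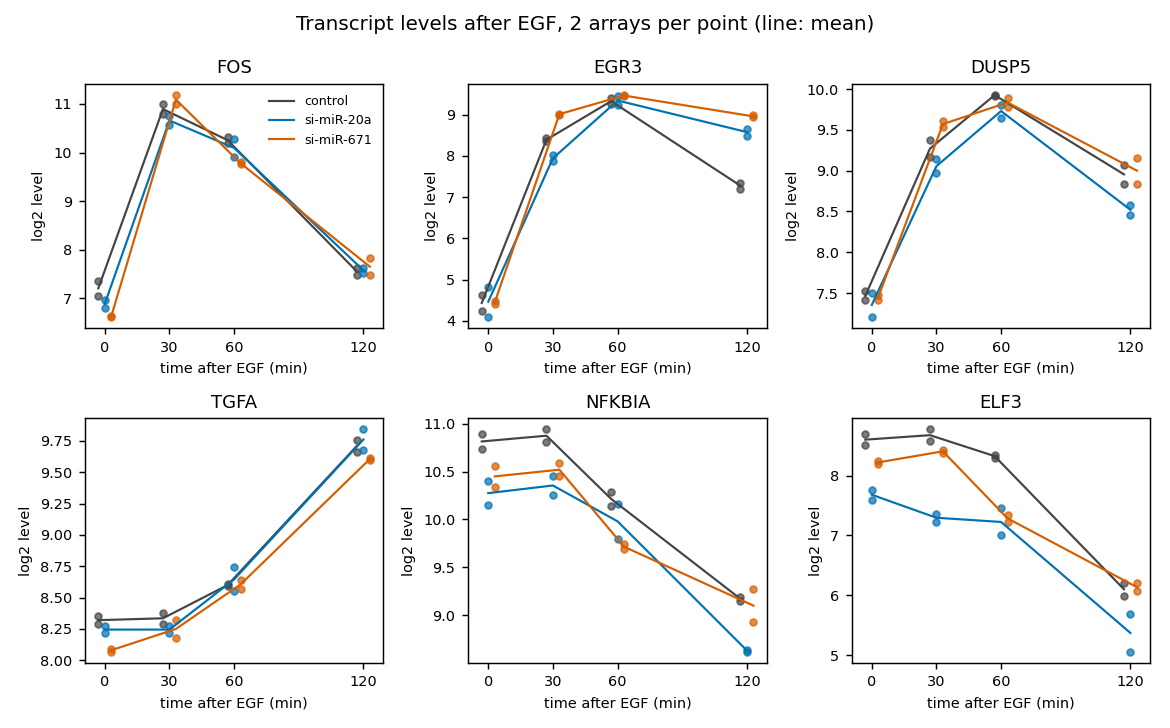
Log2 levels of 6 genes (y axis) against minutes of EGF (x axis) in control, si-miR-20a and si-miR-671 cells, with 1 point per array and lines through the means of 2. FOS rises from 7.21 to 10.9 by 30 min in control, TGFA rises by 1.39 at 120 min, and NFKBIA and ELF3 fall by 1.65 and 2.50 at 120 min.

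Averaged over the 3 transfections (6 arrays against 6), the EGF response held more genes in the same lists. FOS rose by 3.98 ± 0.09 at 30 min, PTGS2 by 3.85 ± 0.07 at 60 min and IL24 by 3.34 ± 0.07 at 120 min, and ELF3 fell by 2.30 ± 0.10 at 120 min. Of 26 immediate early factors 19, 23 and 23 were higher at 30, 60 and 120 min, of 29 feedback attenuators 14, 16 and 21, and of 7 ligands 2, 4 and 5. Adjusted over the list alone the counts were 24, 24 and 23, 16, 21 and 22, and 2, 5 and 5, and the exact permutation test of the list scores gave the smallest p the design allows, 0.0093, each time. Of 18 cytokine genes 10 were higher at 30 min, 10 higher and 2 lower at 60 min, and 6 higher and 9 lower at 120 min, or 12, 12 and 2, and 6 and 9 adjusted over the list alone. Limma called 149 probe sets at 30 min (141 higher), 517 at 60 min (421 higher) and 2607 at 120 min (1387 higher and 1220 lower), of which 72, 160 and 382 changed by at least 1.5-fold. Without the si-miR-671 arrays, an average over fewer arrays chosen after seeing the data, the counts at 30, 60 and 120 min were 95, 398 and 1866. At 120 min 1080 of these were higher and 786 lower. The averages over 3 transfections include the si-miR-671 arrays at 60 and 120 min, which stood apart from 0 and 30 min as described below.

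Cells given si-miR-20a differed from control cells at many genes, averaged over the 4 times. SCEL, a precursor of the cornified envelope, was higher by 1.73 ± 0.11 (3.31-fold, n = 8 arrays against 8), and so was SPRR1B, another gene of that envelope, by 0.97 ± 0.08. The aldehyde oxidase AOX1 was higher by 1.46 ± 0.07, the protease inhibitor SERPINB7 by 1.36 ± 0.05, the cystine transporter SLC7A11 by 0.98 ± 0.05 and the ligand NRG1 by 0.93 ± 0.06. Lower were VNN2 (-2.15 ± 0.18), the chitinase-like CHI3L1 (-1.91 ± 0.10) and CHI3L2 (-1.78 ± 0.14), and SULF1, which edits heparan sulfate (-1.90 ± 0.11). S100A9 and S100A8, the subunits of calprotectin (-1.58 ± 0.11 and -1.48 ± 0.08), and LCN2, which binds siderophores (-1.54 ± 0.10), were lower too. Of 18 cytokine and NF-kappaB feedback genes 13 fell and IL1B rose, the same counts adjusted over the list alone. Among them were CXCL1 at -1.20 ± 0.04, ICAM1, a leukocyte adhesion receptor, at -1.18 ± 0.10, IL6 at -0.93 ± 0.07 and CSF3 at -0.88 ± 0.08 (limma camera adjusted p = 8.6e-07). With an estimated correlation that call was lost (adjusted p = 0.15 with an estimated correlation). The exact permutation test of the list's score, stratified by time, gave an unadjusted p = 0.0015, its smallest. It tests the list's own shift, not its shift against other genes.

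Among the targets of the miR-17 family known from earlier literature, the family of miR-20a, 13 of 37 were higher in si-miR-20a cells and 8 lower, the same counts adjusted over the list alone. EPHA4 (0.71 ± 0.08), ZNFX1 (0.68 ± 0.04), TXNIP (0.63 ± 0.05), the cyclin CCND1 (0.52 ± 0.06) and CDKN1A, which inhibits cyclin-dependent kinases (0.47 ± 0.04), were higher. SMAD7 (-0.53 ± 0.07), BCL2L11 (-0.51 ± 0.07) and MAP3K5 (-0.47 ± 0.06) were lower, and camera did not call the list (adjusted p = 0.13). Of 25 G1/S genes 11 were higher, CCNE2 by 0.59 ± 0.09 and CDC6 by 0.45 ± 0.05, or 13 higher and 1 lower adjusted over the list alone (adjusted p = 0.00023). That call was lost (adjusted p = 0.15 with an estimated correlation).

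In si-miR-20a cells LRIG1 and ERRFI1, which restrain the EGF receptor, were lower by log2 changes of -0.72 ± 0.05 and -0.68 ± 0.07, and SOCS3, which restrains cytokine signalling, by -0.74 ± 0.08. Of 29 feedback attenuators 4 were higher and 11 lower (6 and 11 adjusted over the list alone), and camera did not call that list (adjusted p = 0.053). Nor did it call the immediate early list, with 1 higher and 8 lower of 26 (adjusted p = 0.062), the ligands, with 4 of 7 higher (adjusted p = 0.062), or the p53 targets, with 3 higher and 8 lower of 18 (adjusted p = 0.053). GDF15 (-0.68 ± 0.08) and the death receptor FAS (-0.48 ± 0.06) were among the lower p53 targets. Limma called 4771 of 19460 probe sets (24.5%), 2309 higher and 2462 lower, and the median size of the called changes was 0.28. By at least 1.5-fold 356 changed, 125 up and 231 down. With 0 and 30 min alone, chosen after seeing the data, the count was 2328.

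Cells given si-miR-671 differed from control by fewer calls. SCEL was higher by 1.53 ± 0.11 (2.89-fold, n = 8 arrays against 8), ANXA10 by 1.07 ± 0.08, SREK1IP1 by 0.92 ± 0.06, and FOXA1, a pioneer transcription factor, by 0.82 ± 0.06. TGM1, which cross-links the cornified envelope, was higher by 0.81 ± 0.06. Lower were VNN2 (-1.79 ± 0.18), SULF1 (-1.60 ± 0.11), CHI3L1 (-1.45 ± 0.10), complement factor B, CFB (-1.34 ± 0.04), the cadherin CDH11 (-1.34 ± 0.07) and the acute phase gene SAA1 (-1.30 ± 0.07). Cell cycle genes rose together: 21 of 25 mitosis genes were higher, or 23 adjusted over the list alone, with BUB1B at 0.48 ± 0.07, AURKB at 0.45 ± 0.07 and CDK1 at 0.42 ± 0.08. Camera called the list (limma camera adjusted p = 6.5e-17, and adjusted p = 0.0077 with an estimated correlation). Of 25 G1/S genes 19 were higher, or 20 adjusted over the list alone, with CCNE2 at 0.68 ± 0.09, CDC6 at 0.57 ± 0.05 and MCM5 at 0.55 ± 0.05. Camera called it as well (adjusted p = 1.6e-16, and adjusted p = 0.0019 with an estimated correlation). The exact permutation test of both scores, stratified by time, gave p = 0.0015, the smallest it can give.

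Other lists moved in si-miR-671 cells at the preset correlation and lost their calls with an estimated one. Of 18 cytokine genes 9 were lower and IL24 higher (2 higher and 11 lower adjusted over the list alone, camera adjusted p = 1.3e-05, and adjusted p = 0.1 with an estimated correlation). IL6 stood at -1.10 ± 0.07, CXCL1 at -0.96 ± 0.04 and ICAM1 at -0.83 ± 0.10. Of 31 interferon response genes 8 were lower, CXCL10 by a log2 change of -1.14 ± 0.11 and OAS1 by -0.27 ± 0.04. These were 1 higher and 10 lower adjusted over the list alone (adjusted p = 0.1 with an estimated correlation). Of 18 p53 targets 8 were lower, with the death receptors FAS at -0.38 ± 0.06 and TNFRSF10B at -0.36 ± 0.04. Adjusted over the list alone 1 was higher and 8 lower (adjusted p = 0.13 with an estimated correlation). Of 10 heat shock genes HSPD1, HSPH1, DNAJB1 and HSP90AA1 were higher, or 5 adjusted over the list alone (adjusted p = 0.082 with an estimated correlation). Of 19 adhesion genes 3 were higher and 9 lower, or 3 and 10 adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). Of 37 miR-17 family targets 4 were higher and 11 lower, or 4 and 13 adjusted over the list alone (adjusted p = 0.018, and adjusted p = 0.37 with an estimated correlation).

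Of the miR-671-5p targets from earlier literature, 3 were measured. In si-miR-671 cells SMARCB1 was higher by 0.22 ± 0.05, CHPF2 lower by a log2 change of -0.22 ± 0.05, and FOXM1, at 0.17 ± 0.08, passed adjusted over the list alone (camera adjusted p = 0.6). Without 60 min SMARCB1 was not called (0.062). Limma called 2820 probe sets, 1322 higher and 1498 lower, of which 182 changed by at least 1.5-fold. The count was 1556 without 60 min and 1704 without 120 min. With 0 and 30 min alone, an average chosen after seeing the data, it was 546, and BUB1B (0.34, adjusted p = 0.1) and AURKB (0.37, adjusted p = 0.082) were not called.

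Set against each other, without the control means, the transfections parted at miR-17 family targets, interferon genes and cell cycle genes. Of 37 miR-17 family targets 15 were higher in si-miR-20a than in si-miR-671 cells, or 17 higher and 1 lower adjusted over the list alone. ZNFX1 was higher by 0.77 ± 0.04, LIMK1, a kinase of cofilin, by 0.55 ± 0.06, TGFBR2, a TGF-beta receptor, by 0.52 ± 0.04, and TXNIP by 0.50 ± 0.05 (n = 8 arrays against 8). Camera called the list (adjusted p = 3.1e-09, and adjusted p = 0.026 with an estimated correlation). Against control the list was not called in si-miR-20a cells, and 11 of 37 were lower in si-miR-671 cells, so the gap does not show a rise in si-miR-20a cells alone. Of 31 interferon genes 8 were higher, or 10 higher and 1 lower adjusted over the list alone (adjusted p = 0.0073 with an estimated correlation). IFI44L was higher by 0.81 ± 0.08, IFIT1 by 0.69 ± 0.06 and IRF9, part of the complex that turns on interferon genes, by 0.63 ± 0.05. Against control that list was not called in si-miR-20a cells, with 8 higher and 2 lower (adjusted p = 0.22).

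Mitosis genes were lower in si-miR-20a than in si-miR-671 cells. Of 25 measured 19 were lower, or 23 adjusted over the list alone (camera adjusted p = 3.9e-25, and adjusted p = 0.0029 with an estimated correlation). CENPE stood at -0.54 ± 0.08, CCNA2 at -0.47 ± 0.05 and TOP2A at -0.35 ± 0.04. Against control the list was not called in si-miR-20a cells, with 4 higher and 3 lower (adjusted p = 0.86). Of 25 G1/S genes 5 were lower, or 13 adjusted over the list alone (adjusted p = 0.014 with an estimated correlation). Exact permutation tests of the scores, stratified by time, gave p = 0.0015, the smallest possible, for the miR-17 target and G1/S lists and p = 0.0031 for the interferon and mitosis lists. Beyond the lists, ENPP5 (1.13 ± 0.18), ACER2 (0.78 ± 0.05) and NKIRAS1 (0.75 ± 0.06) were higher. NR4A1 (-0.65 ± 0.12), ELF3 (-0.62 ± 0.09) and GMNN, an inhibitor of replication licensing (-0.55 ± 0.10), were lower. Without 30 min NR4A1 (0.077) and GMNN (0.15) were not called.

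Most differences between the transfections were small, such as that of OAS1, at 0.20 ± 0.04. Limma called 884 probe sets, 464 higher in si-miR-20a and 420 lower, of which 19 changed by at least 1.5-fold. Taken apart by time, which was chosen after seeing the data, it called 1461 probe sets at 0 and 30 min and 219 at 60 and 120 min, 81 of them in both and in the same direction. Further lists passed at the preset correlation and were lost. Of 26 immediate early factors 5 were lower, or 6 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation). Of 18 cytokine genes LIF, PTGS2 and CXCL1 were lower, or 6 adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). Of 8 basal markers 4 were higher adjusted over the list alone (adjusted p = 0.14 with an estimated correlation). Of 29 feedback attenuators 2 were higher and 3 lower, or 2 and 6 adjusted over the list alone (adjusted p = 0.39 with an estimated correlation). Of 19 adhesion genes 3 were higher and 1 lower, or 4 and 1 adjusted over the list alone (adjusted p = 0.34 with an estimated correlation).

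The count of probe sets called between the transfections depended on single arrays. Among si-miR-671 arrays it was 478 and 586 without 0 min replicates 1 and 2, 574 without 30 min replicate 1, 518 without 60 min replicate 1 and 570 without 120 min replicate 2. Among si-miR-20a arrays it was 566 without 0 min replicate 2, 513 without 30 min replicate 1, 528 without 60 min replicate 2 and 1512 without 120 min replicate 1. It was 369 without 0 min, 321 without 30 min and 1616 without 60 min. With pairs of times chosen after seeing the data it was 1461 for 0 and 30 min and 219 for 60 and 120 min. With 60 and 120 min alone ELF3 (0.15), NR4A1 (0.17), GMNN (0.61), TOP2A (0.062) and CCNA2 (0.062) were no longer called.

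**Figure D2:**
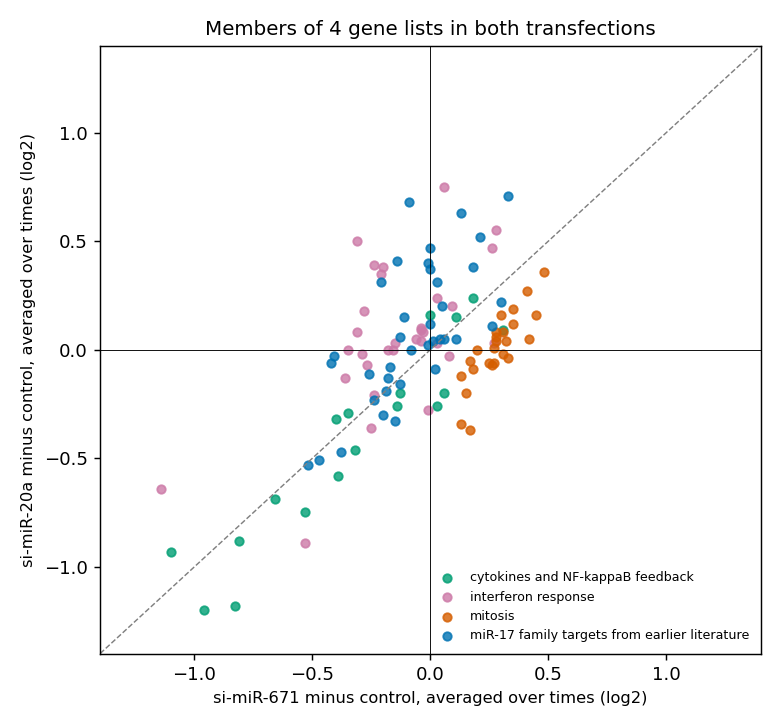
Averaged log2 effect against control of si-miR-20a (y axis) and si-miR-671 (x axis) for the members of 4 lists, 1 point per gene, with a dashed line where both effects are equal. Mitosis genes lie right of 0, where 21 of 25 passed for si-miR-671, and 15 of 37 miR-17 family targets were called higher with si-miR-20a than with si-miR-671.

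Both transfections moved many of the same genes the same way against the shared controls. SCEL, DPYSL3, GPRC5A, SERPINB7 and AOX1 were among the largest rises of each, and VNN2, CHI3L1, CHI3L2, SULF1, SNCAIP, PLPP3 and S100A9 among the largest falls. Of 18417 genes, 972 were higher in both (151 if the calls were independent), 1149 lower in both (177 if independent) and 15 were called in opposite directions. Across genes, which are not independent replicates, the averaged effects correlated at 0.777, where 100 simulations of unchanged groups against the same controls gave a median of 0.497 and a highest of 0.524. Their covariance was 0.0305 against a highest simulated 0.00638, and with the control arrays split by replicate number, so that neither effect used the other's controls, it was 0.0239 and 0.0255 (correlations 0.523 and 0.572).

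At single times the number of probe sets called varied widely. For si-miR-20a, limma called 646 probe sets at 0 min, 992 at 30 min, 1205 at 60 min and 1958 at 120 min (290, 290, 640 and 1013 of them higher). For si-miR-671 it called 105, 89, 1592 and 1086 (44, 37, 602 and 486 higher). These counts rest on 2 arrays against 2 with a pooled spread, and most moved when 1 array was left out. An array of a group outside a comparison enters that comparison only through the pooled spread.

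For si-miR-20a the count of probe sets at 0 min was 251 and 238 without control replicates 1 and 2 and 225 without si-miR-20a replicate 2. At 30 min it was 250 and 412 without control replicates 1 and 2 and 320 and 398 without si-miR-20a replicates 1 and 2. At 60 min it was 461, 407, 633 and 563 in the same order. At 120 min it was 829 without control replicate 1 and 589 without si-miR-20a replicate 2. For si-miR-671 at 0 min the count was 8 and 31 without control 0 min replicates 1 and 2 and 4 and 31 without si-miR-671 0 min replicates 1 and 2. It was 68 without either control 60 min replicate, 69 without either si-miR-671 60 min replicate and 171 without either si-miR-20a 120 min replicate. At 30 min it was 4 and 19 without control replicates 1 and 2 and 5 without si-miR-671 replicate 1. At 60 min it was 582 and 597 without control replicates 1 and 2 and 704 and 514 without si-miR-671 replicates 1 and 2. At 120 min it was 620 without control replicate 1 and 626 and 618 without si-miR-671 replicates 1 and 2.

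**Figure D3:**
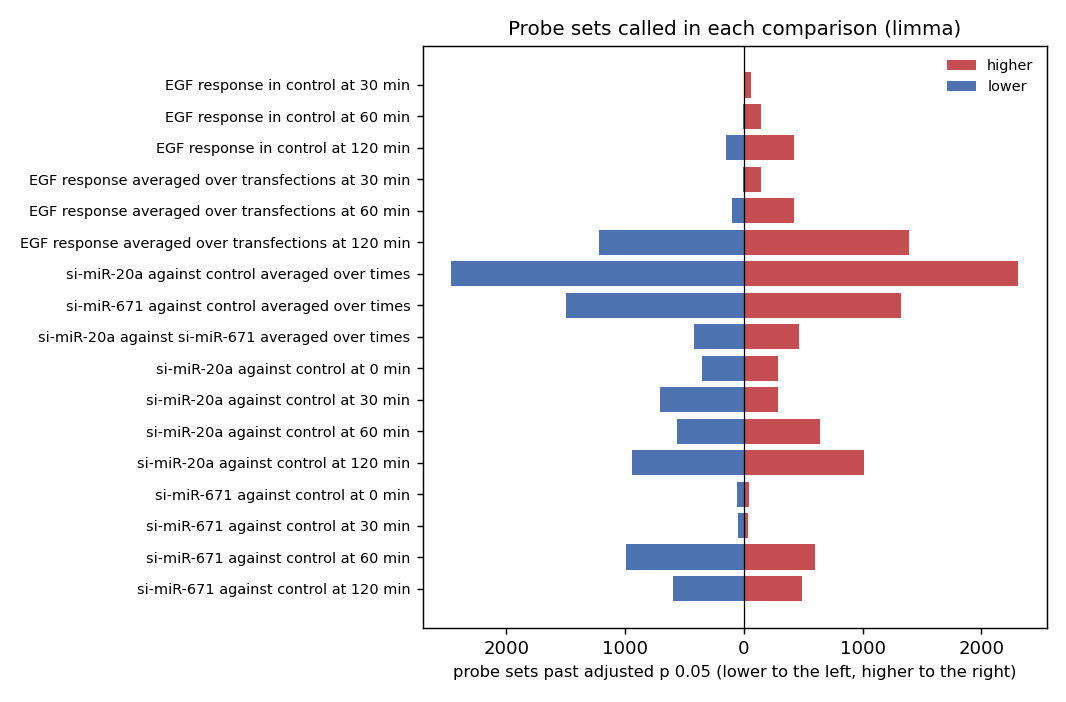
Number of probe sets past an adjusted p of 0.05 in limma (x axis, lower to the left and higher to the right) for each comparison. The averaged si-miR-20a comparison has 4771 and the averaged si-miR-671 comparison 2820, and for si-miR-671 the bars grow from 105 and 89 at 0 and 30 min to 1592 and 1086 at 60 and 120 min.

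Differences of the EGF time course from control were tested gene by gene. In si-miR-20a cells the moderated F called CYP24A1, the enzyme that inactivates vitamin D (adjusted p = 0.015), PTGS2 (adjusted p = 0.042) and IL24 (adjusted p = 0.046). At 120 min their changes from 0 min lay 2.21 ± 0.26, 1.53 ± 0.17 and 1.30 ± 0.18 above those in control (n = 2 arrays per group). CYP24A1 stood at 5.44 at 0 min and 7.40 at 120 min in si-miR-20a cells, and at 6.72 and 6.47 in control. CXCL8 (1.69 ± 0.27), TNFAIP3 (0.84 ± 0.13), TXNIP (0.86 ± 0.14) and EGR3 (1.27 ± 0.25) differed by these amounts at 120 min without passing the F test (adjusted p = 0.12). Of 18 cytokine genes 4 passed the test of 120 min alone, each higher, or 6 adjusted over the list alone (camera adjusted p = 9.9e-09). That call was lost (adjusted p = 0.09 with an estimated correlation).

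The F test for si-miR-20a called 3 probe sets of 19460, those of CYP24A1, PTGS2 and IL24, with 1030 at an unadjusted p under 0.05. The count was 15 without si-miR-20a 120 min replicate 1. It was 1 without control 0 min replicate 1, without either replicate of control 30 min, si-miR-671 30 min or si-miR-671 60 min, and without replicate 1 of si-miR-20a 30 min or 60 min. Limma called 0 without control 120 min replicate 1 or 2, si-miR-20a 60 min replicate 2 or si-miR-20a 120 min replicate 2 (836, 1406, 1214 and 802 at an unadjusted p under 0.05). CYP24A1 was lost without those last 4 arrays (adjusted p = 0.11, 0.18, 0.054 and 0.22) and with array weights (0.14). PTGS2 was lost without 14 of the 16 arrays of the test (0.053 to 0.22) and IL24 without 13 of them (0.067 to 0.37). With the replicate number as a block PTGS2 and IL24 were not called (0.068 each), while CYP24A1 was (0.026). Over the settings other than leaving out 1 array, the adjusted p ran from 0.0042 to 0.14 for CYP24A1, 0.0042 to 0.16 for PTGS2 and 0.016 to 0.41 for IL24.

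In si-miR-671 cells CFB (adjusted p = 0.002) and ACAT1, a mitochondrial thiolase (adjusted p = 0.0065), fell relative to control from 60 min on. Both genes were also among 458 probe sets by which the si-miR-671 arrays at 60 and 120 min stood apart from 0 and 30 min. The cause of that pattern is open. ACAT1 stood at 10.18 and 10.15 at 0 and 30 min and at 9.37 and 9.25 at 60 and 120 min (n = 2 arrays per group). In control it stood at 10.19, 10.15, 10.28 and 10.09, and in si-miR-20a cells at 9.25, 9.29, 9.33 and 9.33. CFB stood at 9.21, 9.18, 8.28 and 8.13 in si-miR-671 cells, against 10.14, 10.05, 10.16 and 9.82 in control. Its single si-miR-20a arrays ran from 8.41 to 8.8. BTN3A1 changed likewise, by -0.69 ± 0.13 and -0.75 ± 0.13 at 60 and 120 min relative to control (adjusted p = 0.044). LIF rose further than in control by 0.94 ± 0.16, 0.92 ± 0.16 and 1.23 ± 0.16 at 30, 60 and 120 min (adjusted p = 0.033), from a lower start (6.04 against 6.77). HBEGF did so by 0.53 ± 0.11, 0.67 ± 0.11 and 0.77 ± 0.11 (adjusted p = 0.044), and DUSP1 by 0.45 ± 0.13, 0.32 ± 0.13 and 1.03 ± 0.13 (adjusted p = 0.033). EGR3 differed by 1.67 ± 0.25 at 120 min without passing (adjusted p = 0.051). TRAFD1 differed by 0.78 ± 0.11 at 120 min and the olfactory receptor gene OR2C3 was called too (adjusted p = 0.044 for both). As a list, the 26 immediate early factors changed more from 0 to 30 min than in control, by a median of 0.29 (camera adjusted p = 2e-15, and adjusted p = 0.01 with an estimated correlation). Part of this was a lower start, as their median lay 0.15 below control at 0 min and 0.14 above it at 30 min (adjusted p = 0.081 and adjusted p = 0.18 with an estimated correlation). FOS stood at 6.63 and 11.09 in si-miR-671 cells and at 7.21 and 10.9 in control. Limma called 0 of them singly and 3 adjusted over the list alone, with 446 of 19460 probe sets at an unadjusted p under 0.05.

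The F test for si-miR-671 called 10 probe sets of 8 genes, among them CFB and ACAT1, with 1776 probe sets at an unadjusted p under 0.05. With the mean of a gene's probe sets it called 4, and TRAFD1, HBEGF and BTN3A1 were not called (0.051 each). Without control 0 min replicates 1 and 2 the count was 4 and 5, without either control 60 min replicate 3, and without control 120 min replicate 2 it was 6. Without si-miR-671 replicates 1 and 2 it was 5 and 4 at 0 min, 6 and 18 at 30 min, 4 and 3 at 60 min and 4 and 4 at 120 min. Without either si-miR-20a 60 min replicate it was 6, and without either si-miR-20a 120 min replicate 22. CFB and ACAT1 were called without any 1 of the 16 arrays of the test. LIF was lost without 12 of them (0.055 to 0.15), DUSP1 without 13 (0.052 to 0.13), TRAFD1 without 14 (0.055 to 0.14), HBEGF without 15 (0.074 to 0.23) and BTN3A1 without each of the 16 (0.06 to 0.15). With the replicate number as a block HBEGF was not called (0.05). Apart from left-out arrays, the highest adjusted p over the settings was 0.019 for CFB, 0.021 for ACAT1 and 0.11 for HBEGF. With all probe sets LIF and DUSP1 (0.093 each) and TRAFD1 and BTN3A1 (0.11 each) were not called either.

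**Figure D4:**
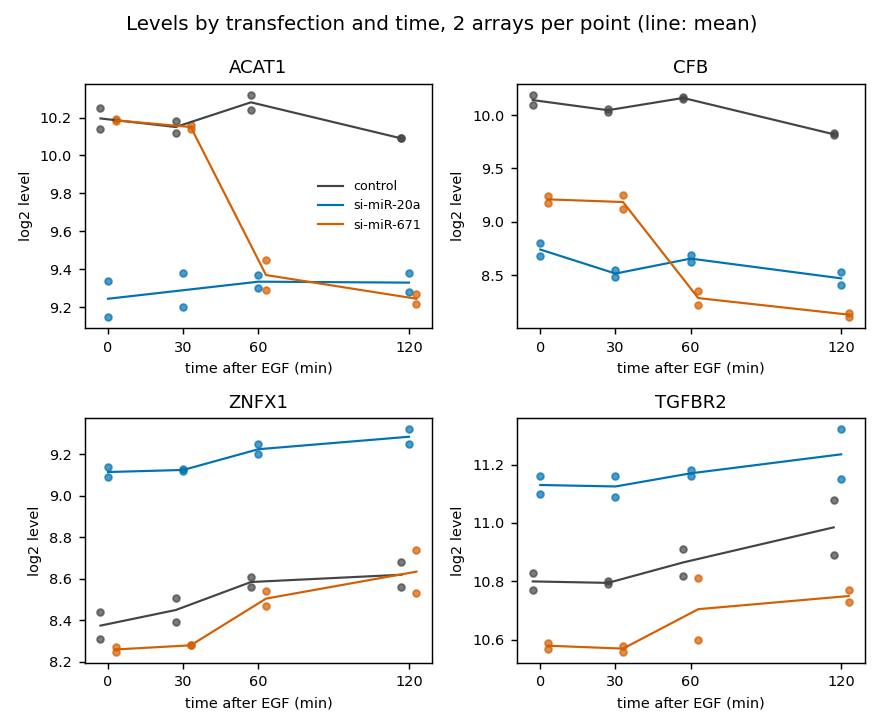
Log2 levels of 4 genes (y axis) against minutes of EGF (x axis) by transfection, with 1 point per array and lines through the means of 2. ACAT1 and CFB in si-miR-671 cells drop between 30 and 60 min, from 10.15 to 9.37 and from 9.18 to 8.28, while ZNFX1 and TGFBR2 lie 0.77 and 0.52 higher in si-miR-20a than in si-miR-671 cells over the 4 times.

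The arrays measured 7 of 15 microRNA host and primary transcripts, which do not measure mature microRNAs. EGF raised MIR17HG, the host transcript of the cluster that holds miR-20a, by 1.02 ± 0.17 at 120 min in control (adjusted p = 0.0022, n = 2 arrays per group). At 30 and 60 min MIR17HG stood 0.37 ± 0.17 and 0.71 ± 0.17 above 0 min, not past the test (adjusted p = 1 and 0.08). MIR221 rose by 0.71 ± 0.11 at 120 min and MIR222 by 0.93 ± 0.19, the latter not called without control 0 min replicate 1 (0.14) or 120 min replicate 1 (0.1). The list was called at 30, 60 and 120 min, with 1, 1 and 3 of 7 higher and 1, 5 and 3 adjusted over the list alone (adjusted p = 0.024, adjusted p = 0.0097 and adjusted p = 0.038 with an estimated correlation). Its single calls were MIR21 at 30 min, lost without control 0 min replicate 2 (0.14) or control 30 min replicate 1 (0.085) or 2 (0.077), and MIR221 at 60 min, lost without any 1 of the 4 arrays (0.076 to 0.26). MIR17HG stood at -0.16 ± 0.08 in si-miR-20a (adjusted p = 0.21) and 0.13 ± 0.08 in si-miR-671 cells (adjusted p = 0.37), neither past the test. Of 12 genes of the small RNA silencing machinery, AGO2, a core Argonaute, rose by 0.51 ± 0.09 at 120 min, a call lost without control 0 min replicate 2 (0.056). In si-miR-20a cells 2 of the 12 were higher and 2 lower (camera adjusted p = 0.7). In si-miR-671 cells 2 were lower, DICER1 by a log2 change of -0.28 ± 0.06 (adjusted p = 0.13).

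Of 8 basal epithelial markers 5 were higher in si-miR-20a cells, SFN by 0.27 ± 0.03 and KRT14 by 0.26 ± 0.03, and CDH3 was lower. Adjusted over the list alone the counts were the same (camera adjusted p = 0.022), and the call was lost (adjusted p = 0.36 with an estimated correlation). In si-miR-671 cells 3 of the 8 were higher and 1 lower (adjusted p = 0.18). Of 12 luminal markers 1 was higher and 2 lower in each transfection (adjusted p = 0.56 and 0.95), and FOXA1 rose with EGF by 1.38 ± 0.12 at 120 min in control. Of 15 mesenchymal and fibroblast markers 2 were higher and 2 lower in si-miR-20a cells (adjusted p = 0.56). In si-miR-671 cells 2 were lower, or 4 adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.1 with an estimated correlation). EGF raised SNAI2 by 1.09 ± 0.11 at 120 min. Of 9 blood and endothelial markers 1 was higher and 1 lower in si-miR-20a cells and 2 were lower in si-miR-671 cells (adjusted p = 0.8 and 0.5). Of 4 ERBB receptors, EGFR was lower in both, by log2 changes of -0.24 ± 0.06 and -0.21 ± 0.06 (list adjusted p = 0.9 and 0.69). In si-miR-671 cells EGFR was not called without 60 min (0.15) or 120 min (0.11), nor without control 0 min replicate 1 (0.06), 60 min replicate 2 (0.06) or 120 min replicate 1 (0.055), or si-miR-671 30 min replicate 2 or 120 min replicate 1 (0.055 each).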

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

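The tests over the miR-17 family targets and the held-out replicates and every test with the olfactory receptor component were chosen after the result, or the data, had been seen. Splitting the control arrays was planned, but the test of that split against simulations, with its bound, was chosen afterwards too.

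In si-miR-671 cells the arrays at 60 and 120 min lay apart from those at 0 and 30 min beyond what EGF did in the other transfections: limma called 458 probe sets (121 higher, 337 lower), against 10 by the same contrast for si-miR-20a and 5 for control. The trend that the olfactory receptor component captures was argued against as the whole cause. With that component as a covariate, 96.3% of the 458 probe sets (441) were still called. For si-miR-20a RNA in these arrays, 316 of the called probe sets had differed between si-miR-20a and si-miR-671 at 0 and 30 min and closed that gap by a median of 123%, but they were picked with the same arrays, and over all genes, with 1 replicate number held out, the gap closed by 95.4% and 109%. RNA mixed in would narrow each gap, on the log2 scale by a share that varies with the gap's size and direction. Over the 37 miR-17 family targets the mean gap stood at 0.11 and later at 0.20, each ± 0.03 between arrays. It closed by -74.4%, interval -296 to 1.66 between arrays and -550 to -2.29 over resampled genes. That argues against such RNA as the whole cause, while a part of it stays open. A stronger transfection effect in these dishes cannot be told apart from the pattern, as 66.7% of the 546 probe sets called at 0 and 30 min lay further from control later, with a median later effect of 129%, and a difference of dish, date or label and an effect of miR-671-5p that depends on EGF time stay open, untested.

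Both transfections moved many of the same genes, 2121 of them in the same direction, SCEL and CHI3L1 included. The bound set beforehand was a covariance 10 times the highest simulated one. The observed one was 4.79 times the highest, so by that bound the simulations alone did not decide on shared control arrays. In the simulations, shared controls gave a median covariance of 0.00571, which leaves 0.0248 of the observed 0.0305. With the controls split, the lower covariance was 29.6 times the highest simulated one. That argues against independent noise of the shared control arrays as the whole cause. A difference of dish or day common to all control arrays would stay in both parts of the split, so it remains open, untested. The trend of the olfactory receptor component was argued against as the whole cause as well, as 99.6% of the shared genes (2112) stayed with it as a covariate. A response to any of the targeting oligonucleotides, an effect of the control oligonucleotide and a function shared by the 2 microRNAs may each remain. No arrays of untransfected cells were analysed here that would part them. The si-miR-671 average also holds the arrays at 60 and 120 min that stood apart from 0 and 30 min. For si-miR-671 limma called 546 probe sets at 0 and 30 min together and 2999 at 60 and 120 min together. What set the later arrays apart may thus add to the overlap, which was not measured at 0 and 30 min alone.

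Differences of the EGF response between si-miR-20a and control passed the F test for CYP24A1 (adjusted p = 0.015), PTGS2 (0.042) and IL24 (0.046), of which PTGS2 and IL24 were not called with a replicate block (0.068 each). Between si-miR-671 and control they passed for CFB (0.002), ACAT1 (0.0065), LIF and DUSP1 (0.033 each), and OR2C3, TRAFD1, HBEGF and BTN3A1 (0.044 each), of which HBEGF was not called with the replicate block (0.05). The change of the immediate early transcription factors from 0 to 30 min, as a list, differed between si-miR-671 and control (camera, adjusted p = 0.01 with an estimated correlation). Part of this was a lower start at 0 min, and their levels at 30 min alone were not called with an estimated correlation. Probe sets without a single gene symbol, 13837 that no comparison of genes used, carried signal too, with 106 called at 120 min of EGF in control and 1430 in si-miR-20a against control. With groups of 2 arrays, no test for a single outlying array was run.

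For each averaged comparison 1 of 100 splits of the same arrays, the real one, gave as many probe sets, which argues against chance labels. The splits exchange single arrays, so they cannot test a difference of dish or day between groups. For EGF at 30, 60 and 120 min the real counts were 149, 517 and 2607 and the highest of the other splits 43, 106 and 587. For si-miR-20a against control they were 4771 and 3019, for si-miR-671 against control 2820 and 1234, and for si-miR-20a against si-miR-671 884 and 412.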

How the results depend on the processing

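The settings with the olfactory receptor component, 1 probe set per gene, pairs of times and EGF without si-miR-671 were tests chosen after the data had been seen. The tests of seed sites and of shuffled sites were not run, as no 3 prime UTR sequences were held, and neither was the log2 of the value plus 16, as the values were log2. Quantile normalization and centring on medians kept each of the 19 counts within 1.5 times. Unless its construction shows it, the cause of a change was not tested.

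Without dim probe sets, which leaves fewer to adjust over, si-miR-20a against si-miR-671 had 1354 calls, si-miR-671 at 0 and 30 min 209 and 137, and the F tests for si-miR-20a and si-miR-671 9 and 40. With all probe sets si-miR-671 at 0 min had 58 and the F tests 1 and 4. With trend and robust these were 176, 12 and 47. With array weights EGF in control at 60 min had 417 calls, si-miR-20a at 30 and 120 min 1525 and 834, si-miR-671 at 0, 30, 60 and 120 min 461, 149, 4187 and 554, and the F tests 0 (limma, 831 at an unadjusted p under 0.05) and 92. The 2 arrays of a group received the same weight, 1.7 for control 60 min and 0.534 for si-miR-20a 120 min. That setting thus weighted whole groups and could not single out a poor array.

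With the replicate number as a block, a pairing the data did not bear out, the F test for si-miR-20a had 1 call, and 4664 of 4771 calls for si-miR-20a and 2726 of 2820 for si-miR-671 were shared.

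A fold of at least 1.5 left 325 calls for EGF in control at 120 min, 72, 160 and 382 for averaged EGF at 30, 60 and 120 min, 356 for si-miR-20a, 182 for si-miR-671 and 19 between them. At 0, 30, 60 and 120 min it left 278, 374, 454 and 612 for si-miR-20a and 57, 56, 580 and 453 for si-miR-671.

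With only the arrays of the groups compared, which leaves fewer degrees of freedom, EGF in control had 10, 25 and 39 calls, averaged EGF at 120 min 1390 and si-miR-20a against si-miR-671 370. Limma called 0 for si-miR-20a at 0, 30 and 60 min (1916, 2921 and 3185 at an unadjusted p under 0.05) and 44 at 120 min. For si-miR-671 it called 0 at 0, 30 and 120 min (1910, 1379 and 2100 at an unadjusted p under 0.05) and 423 at 60 min. The F tests had 1 and 5.

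The F test for si-miR-671 had 4 calls with the mean of a gene's probe sets, 4 with 1 probe set per gene and 16 with the olfactory receptor component, under which si-miR-671 at 0 and 30 min had 181 and 147. Si-miR-20a against si-miR-671 had 369 without 0 min, 321 without 30 min, 1616 without 60 min, 1461 with only 0 and 30 min and 219 with only 60 and 120 min. Si-miR-671 averaged had 1556 without 60 min, 1704 without 120 min and 546 with only 0 and 30 min, and si-miR-20a 2328 with only 0 and 30 min. EGF at 30 min averaged over control and si-miR-20a had 95. The one value that reversed was MIR17HG in si-miR-671 cells, at -0.03 with only 60 and 120 min against 0.13, not past the test in either.

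Leaving out 1 array, with the lone replicate assumed to vary like the other groups, gave 38 to 69, 93 to 175 and 312 to 666 calls for EGF in control at 30, 60 and 120 min, and 122 to 158, 377 to 589 and 1920 to 3309 for averaged EGF. It gave 4121 to 5103 for si-miR-20a, 2219 to 3109 for si-miR-671 and 478 to 1512 between them. At 0, 30, 60 and 120 min it gave 225 to 771, 250 to 1242, 407 to 1476 and 589 to 2841 for si-miR-20a, and 4 to 171, 4 to 124, 514 to 1839 and 618 to 1317 for si-miR-671. The F tests had 0 to 15 and 3 to 22.

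Of 91 calls of gene lists 50 held with an estimated correlation and 41 did not, and 83 held with fry. Among the named genes, all probe sets ended 30 calls, array weights 12, the block 8, quantile normalization 4, centring 4 and only the groups compared 97. Signal over background could not be measured from these values, and 2 arrays per group limit what small changes can be called.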

Other observations

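The component of the olfactory receptor probe sets, like every setting that uses it, is among the tests chosen after the data had been seen.

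Stress and cell cycle lists moved at 120 min of EGF averaged over the transfections (6 arrays against 6). Of 18 unfolded protein and amino acid stress genes 8 were higher, CHAC1 by 0.84 ± 0.10, TRIB3 by 0.76 and XBP1 by 0.54, and SESN2 was lower by a log2 change of -0.59. Adjusted over the list alone 9 were higher and 1 lower (camera adjusted p = 0.00018, and adjusted p = 0.014 with an estimated correlation). Of 25 mitosis genes 10 were lower, TTK by a log2 change of -0.54 and CENPE by -0.41, or 15 adjusted over the list alone (adjusted p = 0.029 with an estimated correlation). Of 17 cholesterol synthesis genes 7 were higher, INSIG1 by 0.70 and HMGCS1 by 0.57, and 3 lower, and camera did not call the list (adjusted p = 0.053). Of 10 heat shock genes 4 were higher, DNAJB1 by 0.40 (adjusted p = 0.094). Of 31 interferon genes 4 were lower, IFIT2 by a log2 change of -0.88, a list call that was lost (adjusted p = 0.2 with an estimated correlation).

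The 357 olfactory receptor probe sets shared a component, of whose variance 58.6% lay between replicates. Its scores ran from -7.73 (si-miR-671 at 120 min, replicate 2) to 4.54 (si-miR-20a at 0 min, replicate 2). Outside the family 1212 probe sets, with a mean level of 7.52, had an absolute correlation with it above 0.8 within groups.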
